A study of Mus musculus with 18 samples.

How the data were processed

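Genomic DNA from the tails of 9 C57BL/6 mice of one family was measured by array comparative genomic hybridization, in which the DNA of a mouse and a reference DNA carry different dyes and compete for the same probes. The family had 1 sire, 1 dam and 7 F1 offspring. Each mouse was hybridised against the same reference male, mouse 12, on 2 arrays of opposite dye, so 18 arrays entered the work. The 2 arrays of a mouse hold the same DNA and count as 1 replicate. Per the labels, the arrays belong to a second screen whose probes were placed densely around places picked in an earlier screen of the same animals, so the probes do not sample the genome evenly.

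The authors' scanner files hold one array each. Per the file headers, spot intensities were extracted with Feature Extraction 10.7.1.1, which subtracted the background and scaled the dyes with a linear factor to give the processed green and red signals. The files also give unscaled median intensities of each spot and its local background, per the file headers. Positions are those of the mouse build mm9, named in the headers of 16 files. The headers of the other files, both of F1 replicate 7, name no build, and their probes and positions are the same. The series' value table deposited by the authors holds log2 ratios with no stated direction. Set against the scanner file of the same array, its values had slopes from -1.00 to -0.96 on log2 of red over green where the mouse was in Cy5, and from 0.91 to 0.99 where the mouse was in Cy3. The table is therefore log2 of reference over mouse, with column medians between -0.002 and 0.012. Correlations were between 0.956 and 0.999 in size, which leaves a further adjustment whose rule is not given in the sources used here. The table was used only as an alternative, and 0 of its columns lacked a sample.

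Log2 of mouse over reference was computed from the processed signals of each array, centred on the median of the autosomal probes, with no loess. Spots marked as outliers were left out, control spots were not used, and spots of one probe were averaged. The mean of both dye orientations is the value of a mouse. The direction follows from the dyes in the labels. Over autosomal probes, arrays of the same orientation correlated between 0.486 and 0.800 among pairs of mice with the mouse in Cy5, and between 0.533 and 0.792 with the mouse in Cy3. The orientations of one mouse, both turned to mouse over reference, correlated between -0.51 and -0.20, and a dye effect of a probe cancels in their mean.

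Each mouse was scanned for runs of probes within tiled blocks, where a gap over 10000 bp starts a new block. A call needed at least 3 probes, a mean log2 ratio of at least 0.3 in size, both orientations of the same sign with at least 0.15 in size, and an interval score of at least 6. The score is the size of the mean times the square root of the number of probes, divided by the noise of the mouse, which was taken from differences of adjacent probes. Calls of the same sign that overlapped between mice were merged into regions. A mouse carries a region where it was called there or its mean over the region met the same limits of size. Regions were then sorted by carriers: F1 only, F1 and one parent, F1 and both parents, parents only, or all 9 mice. As a measure of false calls from noise of single arrays, the same scan was run on the difference of the orientations of each mouse. The mean difference of each probe over the 9 mice was removed first. Copy number cancels in this contrast, and so does any effect shared by both arrays of a mouse, which lay on one slide. Its calls thus do not count false calls that come from the slide or from the DNA of a mouse.

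Region means and probe values of the 7 F1 were tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), and region means of the F1 were tested against those of the parents. A probe needed values in at least 5 F1. The regions were chosen by size on the same values, so the tests by region are not independent of the choice, and a test against 0 leaves out the spread between reference animals because there was 1. The number of F1 carriers was tested against a share of 0.5 with an exact binomial test, two-sided, for regions carried by exactly 1 parent. Calls on the X and Y chromosomes were not made, and the sex of the F1, which the labels do not give, was not used as a group.

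The scan was tested on simulated noise with 200 planted changes over 122455 autosomal probes. All changes of -1.0, -0.58 and 0.58 were recovered (100% each), and 80.0% of those of 0.3, falling to 53.8% at 3 probes. There were 0 false calls, against 80 calls in the dye contrast of the real arrays. The probe test was run on 122453 simulated probes and recovered 98% of changes of -0.58 and 100% of changes of -0.3, 0.3 and 0.58, with 9 false calls. Simulated values were independent between F1, while real F1 of one slide correlated at 0.20 over probes. The 9 false calls therefore do not measure the error rate of the real arrays.

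The rule for the regions named was fixed before the data were examined: at most 12 regions called in F1 only, by interval score, then the 8 other regions with the highest score. The gene lists fixed with it were not run, and no gene is named, because the annotation used here is of another genome build. Correction for GC content was not run for the same reason. Alternatives were background correction by normexp with an offset of 50, loess, the deposited table, centring on the mode, removal of the median of each probe over mice, a filter on dim probes, other limits of the scan, single orientations, another merging rule, slide as a random block and leaving out replicates. The normexp step used median spot signals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used.

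Of 126550 non-control spots on an array, between 99.82% and 99.87% were well above background in both channels, and 0 were saturated. Outlier marks covered between 0.084% and 0.169% of spots on the 16 arrays of the other mice, and 3.84% and 10.9% on those of F1 replicate 7. That mouse had values at 106627 autosomal probes, which is 87.1%, and the others at 99.9% or more. The number of arrays and mice limits the precision. The file names place the sire and the dam together on a slide of their own and the F1 on 4 other slides, and the arrays were scanned on 3 days. Generation and slide cannot be told apart, while the first scan day holds both parents with F1 replicates 1 and 2.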

Results

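Copy number along the autosomes was compared with a reference male in the 9 mice of one family: a sire, a dam and their 7 F1 offspring. The title of the series places the family in a study of males kept under gamma rays at 1 mGy per day for 400 days, while the design text calls the sire of this family non-irradiated. The mice were therefore grouped by their place in the family alone, and no value here is set against dose. The labels give separate animals, so p-values over the F1 measure the spread between siblings, mixed with that between slides. F1 of one slide correlated at 0.73 over regions, and p-values without a slide block treat them as independent. The array carried 122506 different probes, of which 122455 lay on the 19 autosomes, 48 on X and 3 on Y. Of the autosomal probes, 96.8% lay in 731 tiled blocks with a median of 176 probes, a median length of 25.7 kb and a median spacing of 92 bp. Noise per probe, after averaging the dyes, was between 0.044 and 0.056 on the log2 scale in the 9 mice. All positions are of the mm9 build, and gene content is not analysed here.

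The X and Y probes gave the response of the arrays to a known difference. Against the male reference, the 48 X probes of the dam averaged 0.95 ± 0.093 (SD over probes) and those of the sire -0.01 ± 0.056. F1 replicates 1 to 4 had X means of 0.02, 0.01, 0.01 and 0.01, and F1 replicates 5, 6 and 7 had 0.93, 0.93 and 0.96. The means of the 3 Y probes were 0.01 in the sire and -3.62 in the dam. They lay between -0.01 and 0.05 in F1 replicates 1 to 4, and were -3.20, -3.19 and -3.64 in F1 replicates 5, 6 and 7. By these probes F1 replicates 1 to 4 were male like the sire, and F1 replicates 5, 6 and 7 female like the dam. No slide held F1 of both sexes, so among the F1 a difference between the sexes cannot be told apart from one between slides.

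The most probes among the changes that differed between mice were held by a gain on chromosome 4 of the sire, the dam and F1 replicates 3, 4 and 6. It covered 3 neighbouring called regions with 683 probes between positions 101113754 and 101270832, a span of 157.1 kb. These regions were 23.7, 51.9 and 22.8 kb long and lay in separate tiled blocks, so the span was not measured throughout. In the middle region, from 101163990 to 101215885 with 368 probes, the log2 ratio was 0.53 in the sire, 0.54 in the dam, and 0.52, 0.53 and 0.50 in F1 replicates 3, 4 and 6. The other F1 lay between -0.02 and 0.00 there, and the orientations of a mouse differed by at most 0.05. The region from 101113754 to 101137428 (156 probes) had carrier values between 0.47 and 0.51, and that from 101247995 to 101270832 (159 probes) between 0.48 and 0.52. Single probes fell well below these means, and 3 probes from 101119972 to 101120158 averaged 0.16 in the sire, 0.12 in the dam and 0.07, 0.31 and 0.43 in F1 replicates 3, 4 and 6. F1 replicates 1, 2, 5 and 7 had -0.40, -0.42, 0.02 and -0.16 there. The next probes on either side, at 100957022 and 101755962, lay between -0.05 and 0.09 in the 9 mice, so the ends of the gain fall in untiled sequence. Carriers and other mice were thus separated by far more than the noise, with 3 of 7 F1 among the carriers.

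**Figure D1:**
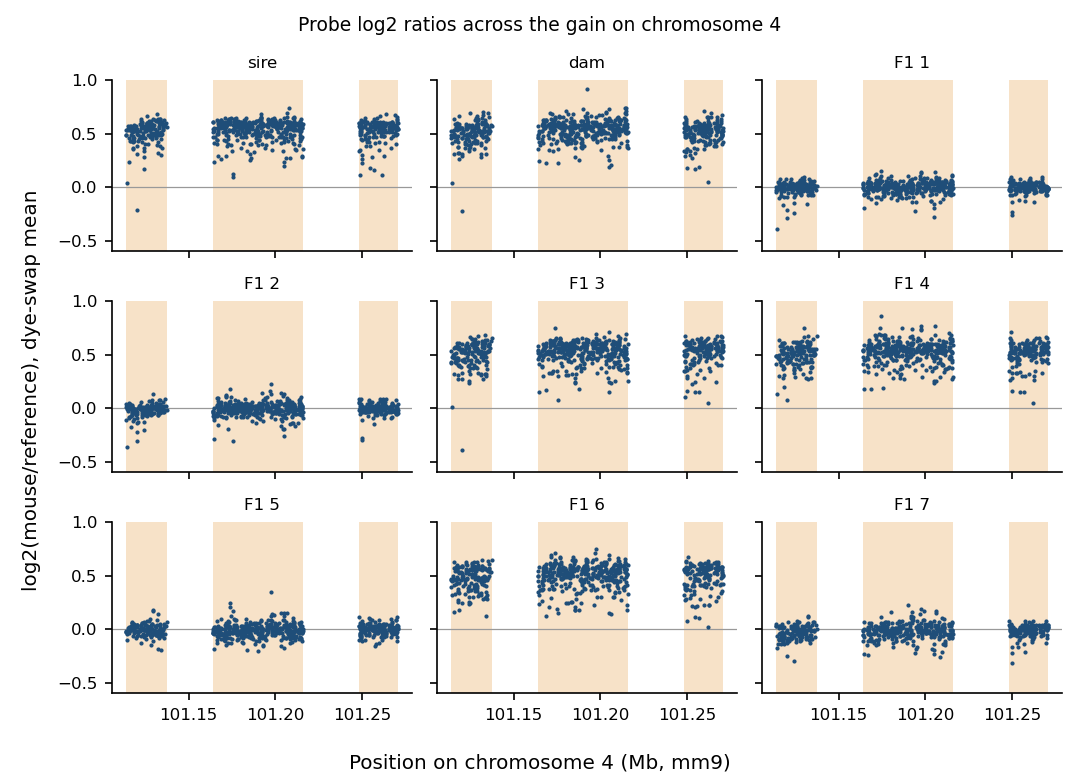
Log2 ratio of mouse over reference (dye-swap mean) against position on chromosome 4 (Mb, mm9), one panel per mouse. Points are probes and shaded spans are the 3 called regions; the sire, the dam and F1 replicates 3, 4 and 6 lie near 0.5 and F1 replicates 1, 2, 5 and 7 near 0.

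A loss on chromosome 3, from 40649701 to 40698989 (33 probes, 49.3 kb), was carried by the dam and by 4 of 7 F1. The log2 ratio was -0.50 in the dam and -0.61, -0.63, -0.58 and -0.60 in F1 replicates 3, 4, 5 and 6. In the sire it was -0.01, and in F1 replicates 1, 2 and 7 it was -0.01, 0.01 and 0.01. Orientations differed by at most 0.04. With the median of each probe over the mice removed, which takes out what most mice share, F1 replicate 4 had -0.13. Within carriers single probes spread widely, with an SD between 0.19 and 0.22, and the 239 probes beside the loss in the same block had medians between -0.02 and 0.00 in the 9 mice.

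**Figure D2:**
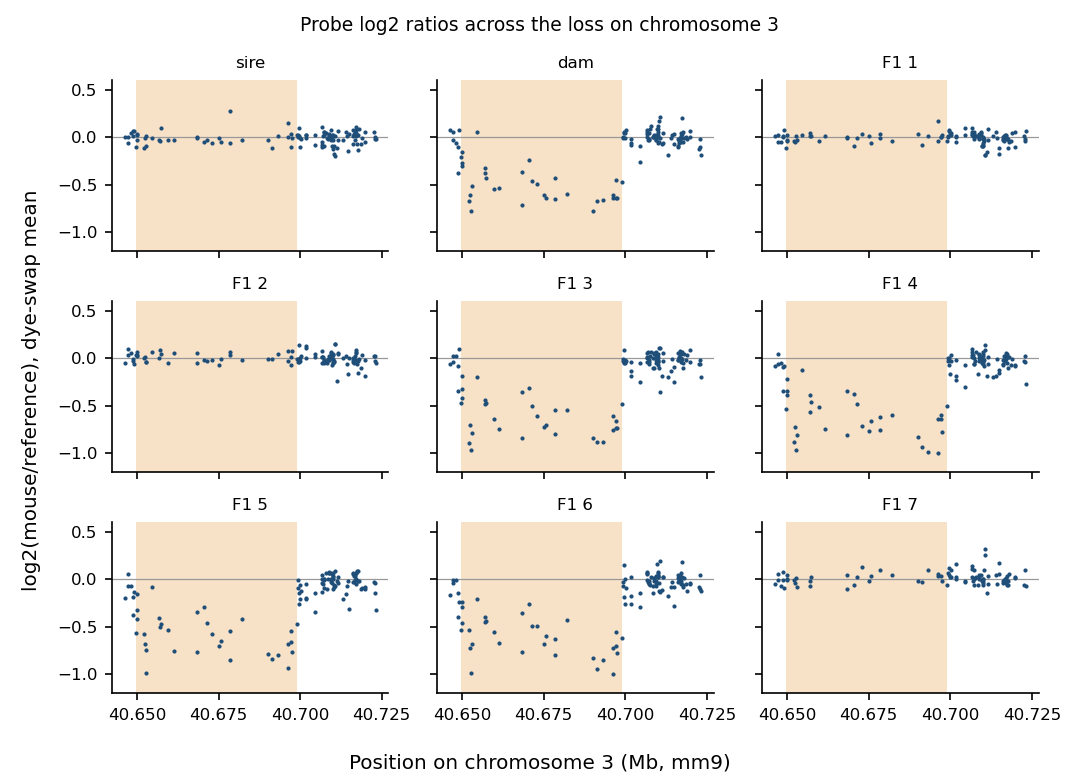
Log2 ratio of mouse over reference (dye-swap mean) against position on chromosome 3 (Mb, mm9), one panel per mouse. Points are probes and the shaded span is the called loss; the dam and F1 replicates 3, 4, 5 and 6 average between -0.63 and -0.50 within it, and the other mice lie near 0.

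A second loss on chromosome 3, from 25421508 to 25456562 (15 probes, 35.1 kb), was carried by the dam, at -1.18, and by F1 replicates 5, 6 and 7, at -1.28, -1.28 and -1.10. The sire lay at 0.00 and the other F1 between 0.00 and 0.04. Single probes reached -3.94 in F1 replicate 5, and the 4 carriers are the mice with low Y probes. The region shared its profile over the 9 mice with 13 other regions.

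On chromosome 9, from 74329817 to 74330215 (6 probes, 0.40 kb), the sire had -0.69, the dam -0.08 and all 7 F1 lay between -0.32 and -0.22. The F1 mean was -0.29 ± 0.032 (SD, n = 7), and limma gave an adjusted p of 0.00058 against 0. The lowest single probe was at -2.41 in the sire and between -0.94 and -0.48 in the F1, against -0.19 in the dam. Without its lowest probe the sire had -0.34, and with the median of each probe over the mice removed -0.40.

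Regions on chromosome 14 were lower than the reference in the whole family. The strongest, from 53752398 to 53764803 (15 probes, 12.4 kb), had -0.49 in the sire, -0.46 in the dam and an F1 mean of -0.45 ± 0.009 (SD, n = 7), with a limma adjusted p of 1.9e-05. In all, 8 regions with 119 probes between 53752398 and 54244001 were called in all 9 mice, with values from -0.49 to -0.14. The span was not lower throughout: the stretch from 54151194 to 54182168 within it held 6 regions, 2 gains and 4 losses. All of these values are relative to 1 reference animal, and no other reference was hybridised. No annotation of this build was at hand, so whether these regions lie in a locus that rearranges in blood cells was not checked, and the values are not read as inherited copy number.

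The last region named among those with the highest scores was a gain on chromosome 17 from 78328236 to 78328872 (10 probes, 0.64 kb). Its values were graded: 0.60 in the dam, 0.25 in the sire, 0.44, 0.59, 0.30 and 0.46 in F1 replicates 3, 4, 6 and 7, 0.14 in F1 replicate 5, and -0.15 and -0.06 in F1 replicates 1 and 2. It shared this profile with 35 other regions. With the median of each probe over the mice removed, the value of the dam was 0.29.

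Across the autosomes, 1157 calls in the 9 mice merged into 359 regions, 98 gains and 261 losses. That split moved with the processing: removing the median of each probe over the mice gave 169 gains and 74 losses, and the mouse in Cy3 alone 437 and 308. Most were short: 288 regions, or 80.2%, held 3 or 4 probes, and the median length was 328 bp. The dye contrast, in which copy number and any effect shared by both arrays of a mouse cancel, gave 80 calls and 57 regions. With at least 5 probes in a merged region there were 71 regions against 12 in the dye contrast, and with at least 10 there were 21 against 1. By carriers, 137 regions fell in F1 only, 89 in F1 and one parent, 91 in F1 and both parents, 33 in parents only and 9 in all mice. Calls per mouse were uneven: 142 in the sire, 191 in the dam, 174, 154, 191 and 107 in F1 replicates 1 to 4, and 61, 67 and 70 in F1 replicates 5 to 7. Both counts of regions moved with the limits of the scan. A minimum mean of 0.4 gave 167 regions with 59 in F1 only, and a minimum of 0.2 gave 824 and 368. By a limit chosen after the values were seen, 113 of the 359 regions, and 47 of the 137 called in F1 only, rested on a single probe, in that the top mouse had no mean of at least 0.15 in size without its strongest probe.

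**Figure D3:**
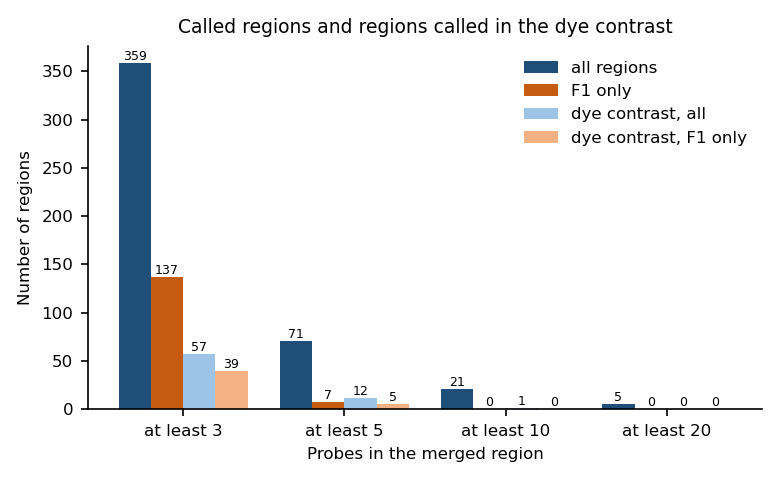
Number of merged regions by the least number of probes they hold, for all regions, regions called in F1 only, and the same classes in the dye contrast. The bars for F1 only fall from 137 at 3 probes to 7 at 5 and 0 at 10, against 39, 5 and 0 in the dye contrast.

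Whether F1 carried changes that both parents lacked is the question the study's title sets. All 137 regions called in F1 only held at most 7 probes, with a median length of 289 bp. The longest spanned 6460 bp, and 8 reached 1000 bp, against 2 in the dye contrast. Among them were 48 gains and 89 losses, and 88 were called in a single F1. The dye contrast gave 39 regions of this class, out of 57, against 137 out of 359 here. With 7 F1 and only a sire and a dam, more calls private to the F1 arise by number alone, and 33 regions fell in parents only. The count of 137 is thus not by itself an excess in the F1. When each call itself had to hold at least 5 probes, the scan gave 35 regions in F1 only against 9 in the dye contrast. Among the merged regions of the first scan, 7 held at least 5 probes against 5 in the dye contrast, and 0 held at least 10. When each call had to hold at least 10 probes, the scan gave 7 regions in F1 only against 1 in the dye contrast. Of these, 4 lay on chromosome 14 between 54108715 and 54332250, where the parents had values between -0.27 and -0.19 that missed the limit. The other 3 lay on chromosome 4 from 30867871 (F1 replicate 7 at 0.30, sire -0.11, dam -0.15), chromosome 7 from 70749442 (F1 replicate 4 at 0.34, sire 0.17, dam 0.21) and chromosome 9 from 83988029 (F1 replicate 6 at -0.32, sire -0.03, dam -0.10). The first overlaps the dim named gain on chromosome 4, and the last holds the low probe of the named loss on chromosome 9.

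The 12 named regions of this class fell into groups. For 3 of them, on chromosome 9 from 83988512 to 83988941 (4 probes), chromosome 1 from 178081462 to 178081799 (3 probes) and chromosome 16 from 40851245 to 40852029 (6 probes), the carriers were F1 replicates 5, 6 and 7, the mice with low Y probes. On chromosome 9 these had -0.67, -0.69 and -0.36, the dam -0.18 and the sire -0.03. The lowest probe was at -2.51, -2.54 and -0.96 in these F1, while the medians of the probes were -0.08, -0.13 and -0.11. On chromosome 1 they had -0.54, -0.56 and -0.77, the dam -0.17 and the sire 0.01. The lowest probe was at -1.68 and -1.72 in F1 replicates 5 and 6, with medians of 0.03 and -0.01, and F1 replicate 7 had a value at only 1 of the 3 probes. On chromosome 16 they had -0.24, -0.23 and -0.22, the dam -0.10 and the sire 0.00, with lowest probes of -1.32, -1.39 and -0.93 and medians of -0.04, -0.02 and -0.02 in the F1. These losses thus rest mostly on 1 low probe, and the median probe of the carriers with more than 1 probe lay between -0.13 and 0.03. In each the dam thus lay below the sire on the same slide, without reaching the limit for a carrier. The lowest probe of the dam was at -0.81, -0.66 and -0.73 on chromosomes 9, 1 and 16. That of the sire was at -0.07, -0.01 and -0.08. A low probe was thus present in the dam as well, and whether it was the same probe as in the F1 was not checked here.

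Another 6 held probes that were not well above background on all arrays. On chromosome 4 the loss from 30872900 to 30873248 was -0.65 in F1 replicate 3, with -0.39 in the dam, and the loss from 30874394 to 30874800 was -0.55 in F1 replicate 2, with 0.45 in the dam. Orientations of a mouse differed there by up to 1.25 and 1.12. In both, 0 of 3 probes were well above background on all arrays. A gain beside them, from 30868459 to 30870442 (7 probes, of which 2 were bright), reached 0.38 in F1 replicate 7 and 0.24 in F1 replicate 6. The gain on chromosome 7 from 47257219 to 47257330 was 0.50 in F1 replicate 2, and the other F1 lay between -0.42 and -0.12. The gain on chromosome 18 from 42507482 to 42507798 was 0.50 in F1 replicate 2, and the loss on chromosome 8 from 17170198 to 17170686 was -0.55 in F1 replicate 7. Both means were carried by 1 of 3 probes, at 1.44 and -1.55, and the medians were 0.05 and -0.09. With normexp these 6 values came to -0.04, -0.08, 0.03, -0.04, 0.02 and -0.04 in the same order.

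In the remaining 3, the parents lay on the same side as the carriers. On chromosome 3 from 129620717 to 129620841 (3 probes) the F1 mean was 0.34 ± 0.126 (SD, n = 7), F1 replicate 5 had 0.54, and the parents had 0.13 and 0.14. With the median of each probe over the mice removed, F1 replicate 5 had 0.27. On chromosome 9 from 24206691 to 24206957 (3 probes), F1 replicates 1, 2 and 3 lay between -0.47 and -0.40, and the sire and dam had -0.28 and -0.25. Without its lowest probe, at -1.13, F1 replicate 2 had -0.14. On chromosome 8 from 17172699 to 17173047 (4 probes, 1 of them dim), F1 replicates 1 and 2 had -0.36 and -0.29, and the sire and dam had -0.19 and -0.14. With normexp the value of F1 replicate 1 was -0.16.

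**Figure D4:**
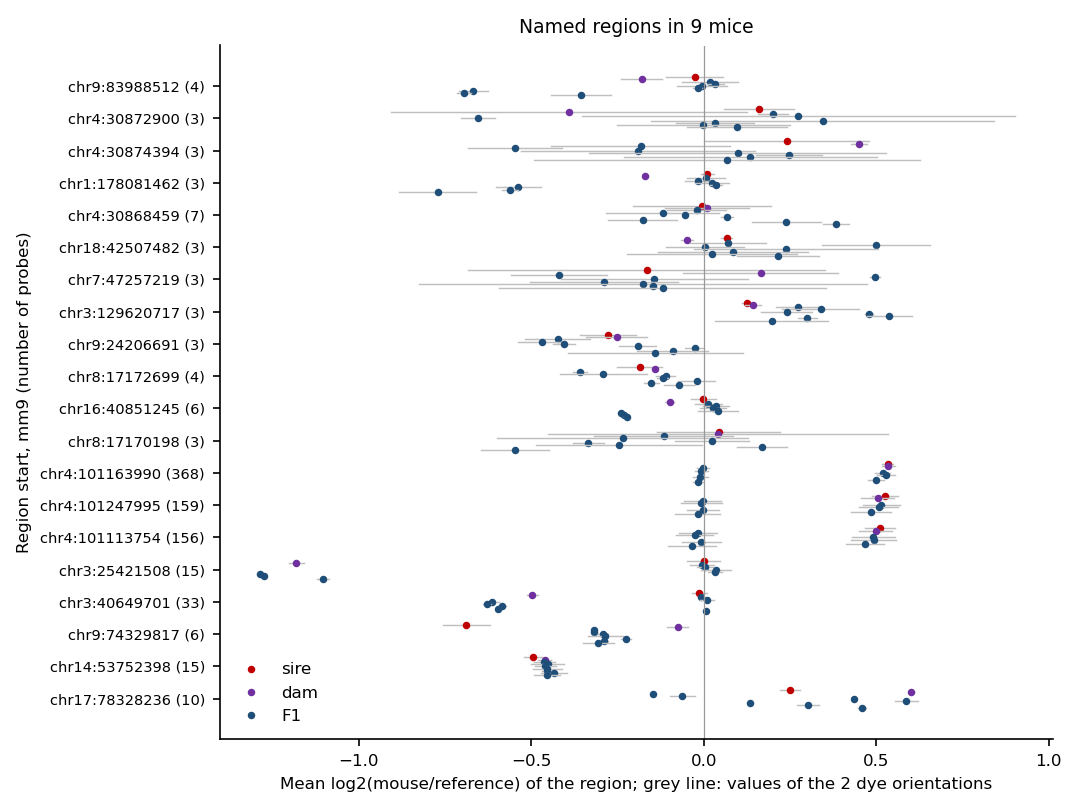
Mean log2 ratio of mouse over reference in each of the 20 named regions (start in mm9 and number of probes at left), with the 12 regions called in F1 only at the top. Dots are mice (sire red, dam purple, F1 blue) and grey lines join the values of both dye orientations; the long regions on chromosomes 3 and 4 split the mice into separate groups, and the lines are longest in 4 short regions on chromosomes 4, 7 and 8.

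Many regions shared their pattern over the mice, and this grouping was chosen after their values were seen. Of the 359 regions, 275 (76.6%) fell into 4 profiles of at least 10 regions that correlated over mice with a mean of at least 0.7. The largest held 199 regions on 19 chromosomes, 195 of them losses, with a median of 3 probes. Its median was -0.28 in both parents, -0.30, -0.30, -0.31 and -0.19 in F1 replicates 1 to 4, and 0.04, -0.07 and -0.14 in F1 replicates 5 to 7. A profile of 36 regions on 14 chromosomes had medians of 0.16 in the sire, 0.42 in the dam and -0.15, -0.09, 0.28, 0.39, 0.09, 0.27 and 0.32 in the 7 F1. Another profile of 26 gains, all in F1 only, had medians from 0.09 in the parents to 0.32 in F1 replicate 4. The last held 14 losses on 10 chromosomes, with -0.30 in the dam, -0.34, -0.35 and -0.40 in F1 replicates 5, 6 and 7, and between -0.01 and 0.01 in the rest. These profiles held 95 of the 137 regions called in F1 only.

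**Figure D5:**
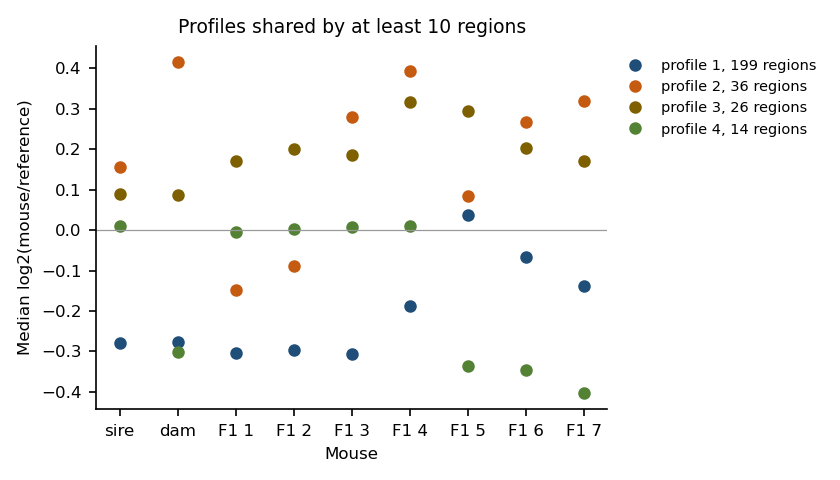
Median log2 ratio of mouse over reference in each mouse for the 4 profiles shared by at least 10 regions. Points are medians over the 199, 36, 26 and 14 regions of a profile; the largest lies between -0.31 and -0.19 in the parents and F1 replicates 1 to 4.

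The mean of the F1 differed from the reference in 266 of 359 regions (limma adjusted p under 0.05), 50 higher and 216 lower. With the slide as a random block 151 passed. Among the named regions, the losses on chromosome 3 from 40649701 (-0.34 ± 0.099, SE, limma adjusted p = 0.014) and from 25421508 (-0.51 ± 0.19, SE, limma adjusted p = 0.035) passed. So did the middle and right parts of the chromosome 4 gain, both with a limma adjusted p of 0.045, while the left part had 0.055. With the slide as a random block, both losses on chromosome 3 had a limma adjusted p of 0.047, and the left, middle and right parts of the chromosome 4 gain no longer passed, at 0.22, 0.20 and 0.20. The gains on chromosome 3 from 129620717 and chromosome 17 passed with limma adjusted p of 0.00082 and 0.028, which the block raised to 0.035 and 0.052. In all, 14 of the 20 named regions passed, and 7 with the block, among them the regions on chromosome 9 from 74329817 (0.010) and chromosome 14 (0.00039). These last regions were carried by all 7 F1. The means of the other named regions join carriers and other mice, so their spread is that of a change present in only some F1.

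Over single probes, 10274 of 122453 differed from the reference in the F1 mean by limma at the same threshold, 3648 higher and 6626 lower. Their median size was 0.083, and 410 of them reached 0.3. The count fell to 6169 with the slide as a random block. It fell to 4124 without F1 replicate 3, 4255 without F1 replicate 4, 6154 without F1 replicate 6 and 5445 without F1 replicate 7.

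The F1 and the parents differed in 0 of 359 regions by limma, with 9 regions at an unadjusted p under 0.05 and a smallest adjusted p of 0.288. The middle part of the chromosome 4 gain averaged 0.22 in the F1 and 0.53 in the parents (difference -0.32 ± 0.18, SE, limma adjusted p = 0.697). Generation is tied to slide here, and with the slide as a random block 1 region had an unadjusted p under 0.05. With scan day as a block the count stayed at 0, with 40 regions at an unadjusted p under 0.05. Within the first scan day, which holds both parents and F1 replicates 1 and 2, 4 regions passed, each lower in the F1. These were the 3 parts of the chromosome 4 gain and a 3-probe region within it, with differences between -0.55 and -0.52 and limma adjusted p of 0.013. F1 replicates 1 and 2 are 2 of the 4 F1 without that gain.

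Transmission from a single carrier parent was tested for 119 regions, 36 from the sire and 83 from the dam. The number of F1 carriers was set against an equal chance of carrying the region or not. After adjustment 0 regions passed the exact binomial test, with 33 at an unadjusted p under 0.05. With 7 F1, the smallest p a region can reach is 0.016, and the smallest adjusted p was 0.056, which is as low as it can fall with 33 of 119 regions at that p. At that count of regions none could pass. The 0 is therefore no sign of equal transmission. Of the 119, 30 were carried by 0 of 7 F1 and 3 by all 7, with a mean of 2.02 carriers. Under an equal chance these extremes would be about equally common, as would 1 and 6 carriers, which had 20 regions and 1. Likewise 2 carriers had 21 regions against 3 with 5 carriers, and 3 carriers had 28 against 13 with 4. As a set the regions thus leaned to few carriers, but the set was not tested as a whole. An equal chance holds only for a true change on 1 copy of a parent, and 8 of the 119 regions held at least 10 probes. A false call in a parent adds a region of few carriers, and regions of a shared profile are not independent. The lean is therefore no sign of unequal transmission. The loss from 40649701 on chromosome 3 passed to 4 of 7 F1, and the region on chromosome 9 from 74329817, carried by the sire, to 7 of 7.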

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

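All tests of explanations in this part were chosen after the patterns were seen. Over the 7 F1, 27 values were searched for a single mouse far from the rest, and 6 were found. Chance marks about 1 in 20 groups of unselected values, a rate that does not apply to the 4 that are of regions chosen for their scores. F1 replicate 7 stood apart with 18619 spots marked as outliers over both arrays and with 106627 autosomal probes measured. F1 replicate 3 stood apart at -0.65 in the chromosome 4 region from 30872900, and F1 replicate 2 at 0.50 in the chromosome 7 region from 47257219, both of dim probes. F1 replicate 5 stood apart at -0.22 in the chromosome 9 region from 74329817, and F1 replicate 6 at -0.43 in the chromosome 14 region from 53752398. In these last regions the F1 as a whole lay between -0.32 and -0.22 and between -0.46 and -0.43.

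The first pattern weighed was the set of 14 losses shared by the dam and F1 replicates 5, 6 and 7. An effect of the slide is argued against, since dam and sire lay on one slide and differed where F1 values alone picked the regions. In the 15 loss regions where F1 replicates 5, 6 and 7 lay below the other F1, the dam was below the sire in 14, with a median difference of -0.27, against 139 of the 311 other regions with an F1 carrier and a median of 0.01. For the strongest of them, on chromosome 3 from 25421508, the loss of 1 autosomal copy inherited from the dam is argued against by the lowest F1 probe value of -3.94, because the sire lay at 0.00 and would leave each F1 a copy. Sequence shared with the Y chromosome is a candidate explanation that stays open. The 4 mice of low Y probes lay below all others in 14 loss regions, while the highest of the other splits, among 126, gave 68, so the first bound set for this test was not met; 66 of those 68 belong to the largest shared profile, which makes that bound a poor one, and no sequence was used here to decide. For the other 13 regions inheritance from the dam was not tested.

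The second pattern was the loss profile shared by 199 short regions on 19 chromosomes. Independent inheritance of regions on different chromosomes is argued against: the first component held 58.1% of the F1 variance of all regions, and at most 33.2% in 100 shufflings by chromosome. Scan day as the whole cause is argued against as well, since slides 3 and 4, scanned on the same day, differed by 0.23, while slides 2 and 3 of different days differed by 0.05. A slide or hybridisation effect may account for the profile, as mice of one slide lay as close as they did in an exact share of 0.032 of the 945 pairings of the mice (30 pairings). The F1 that shared a slide were also of one sex by the X and Y probes, so for the F1 the pairings cannot tell slide from sex. The sire and the dam, of different sex on one slide, both had a median of -0.28 in this profile. A biological difference between the mice of different slides stays untested.

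The third pattern was the 137 regions called in F1 only. Noise of single arrays as the whole cause is argued against, because the dye contrast gave 39 such regions. Dim probes as the whole cause are argued against too, since the value of the top mouse fell under 0.15 with normexp in 39 of the 137. Only 35 of the 137 held a probe that was not well above background on all arrays. Whether a change in a parent below the limit of a call accounts for them stays open. A parent value of the same sign of at least 0.15 was present in 82, but 56 of these belong to the largest shared profile, weighed above. Outside it 26 of 76 regions had one, while 13 had a parent value that far on the opposite side. Without such a parent value or a fall with normexp, 31 regions remained. A fall with normexp does not show that a call was false, as the offset draws ratios of dim probes toward 0. Most of them lay in a shared profile, a grouping made from these same values that does not by itself account for them. The profile of 26 gains, all in F1 only, was not tested on its own. Outside all shared profiles 3 of the 31 remained, each of 3 probes. On chromosome 13, from 119624340, F1 replicate 2 had 0.32 and the sire 0.15, just under that limit. On chromosome 4, from 101119972, the region lies inside the long gain, and its carriers, F1 replicates 1 and 2, lack that gain. On chromosome 8, from 17169889, F1 replicate 6 had 0.30, the sire 0.15, also just under it, and 1 of 3 probes was dim. F1 replicate 3 had 0.21 there, and F1 replicate 7 had -0.65, which is larger in size and of the opposite sign. Each of these 3 regions thus lies near a limit or inside another change, and new changes in the F1 were not decided by these arrays.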

How the results depend on the processing

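Settings on length, shared profiles and scan day, the 10-probe limit in the dye contrast, the random slide block against the parents, the counts without the calls of F1 replicate 7 and without strongest probes were chosen after seeing the data. Counts are given as all regions and then F1 only, against 359 and 137. They stayed within 1.5 times under normexp, loess, the deposited table, mode centring, the dim filter (303 and 102), removal of probe medians (243 and 201), merging by an overlap of 0.5 of both lengths (483 and 185), and without F1 replicate 7 (349 and 127). With probe medians removed, the counts moved in opposite directions, and most of the regions left were called in F1 only. A count within 1.5 times does not show that the same regions were called. Scores of 5 and 8 changed nothing, as the other limits already exceed them. They moved to 115 and 35 with calls of at least 5 probes, 31 and 7 with at least 10, 824 and 368 with a mean of 0.2, 167 and 59 with 0.4, 678 and 331 with the mouse in Cy5 alone, 745 and 312 in Cy3 alone, 45 and 8 for lengths of at least 1000 bp, and 84 and 42 without shared profiles. Where the top mouse had to keep 0.15 without its strongest probe, all regions stayed within 1.5 times at 246, and F1 only moved to 90. Removing probe medians turned 98 gains and 261 losses into 169 and 74, and Cy3 alone gave 437 and 308. The cause was not tested. The 80 calls of the dye contrast became 18 with 5 probes, 1 with 10 and 215 with a mean of 0.2.

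The count of 266 regions differing in the F1 fell to 151 with the slide as a random block (correlation 0.73) and lay between 188 and 264 without each F1 replicate; the 10274 probes fell to 6169 with the block and lay between 4124 and 9793. F1 against parents stayed at 0 under normexp, loess, each left-out mouse and both blocks, and gave 4 within the first scan day. Transmission gave 0 with carrier limits of 0.2 and 0.4 as well, but 7 F1 set the smallest p at 0.016, and too few regions reached it for any to pass (smallest adjusted p 0.068 and 0.076), so this is no sign of stability. Over named regions, 124 values of the top mouse moved by less than the SD of both orientations, 32 moved by more, and 1 turned: the chromosome 7 gain of F1 replicate 2 became -0.045 with normexp. The 124 include 20 values with the mouse in Cy5 alone and 20 in Cy3 alone. A single orientation always lies within that SD of the mean of both, so these values are no sign of stability. Of 20 named regions, 7 fell under 0.5 of their size with normexp, whose offset shrinks dim ratios, and 8 with probe medians removed. With the dim filter 4 of 17 did, and the other 3, on chromosomes 4 and 7, lost all their probes. Removing probe medians takes out what most mice share, and brought the chromosome 4 gain from 0.54 to 0.07 and the chromosome 14 loss from -0.49 to -0.03. Correction for GC content was not run, and signal over background limits the regions of dim probes.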

Other observations

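The measures in this part were chosen after the values were seen. Some short stretches held gains and losses in different mice side by side. On chromosome 4, 6.93 kb from 30867871 to 30874800 held 11 regions, 5 gains and 6 losses, with calls in all 9 mice, and 7 of them were called in F1 only. On chromosome 2, 3.56 kb from 70082900 to 70086460 held 8 regions, 4 gains and 4 losses, with calls in 8 mice. On chromosome 7, 1.60 kb from 47256734 to 47258337 held 4 regions, all called in F1 only. On chromosome 8, 3.16 kb from 17169889 to 17173047 held 3, also all in F1 only. In the named regions of the chromosome 4 and 7 stretches the median green signal was between 14.4 and 38.6, against 1061 over autosomal probes, while in those of the chromosome 8 stretch it was 489 and 929.

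For the profile of 36 regions, mostly gains, an effect of the slides was not decided. Mice of one slide differed by a root mean square of 0.18 over these regions, against 0.30 in the median pairing, and an exact share of 0.094 of the 945 pairings was as close. Its longest gains, of 10 to 12 probes, spanned 603 to 1015 bp on chromosomes 3, 5, 10, 13, 15 and 17, and no other explanation was tested.

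On the chromosome 4 gain, both parents had about the same value as the F1 carriers, and no F1 exceeded 0.53 in the middle part. On the chromosome 3 loss from 40649701, the dam at -0.50 lay above the 4 F1 carriers, which were between -0.63 and -0.58. The dam and the F1 lay on different slides, and this difference was not tested.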
